A study of Mus musculus with 6 samples.

How the data were processed

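Total RNA was extracted with Trizol from wild-type and Med23 knockout mouse ES cells and turned into biotinylated cRNA for Affymetrix arrays, per the labels' protocols. The processed values of 6 arrays, 3 per genotype, were used. The authors deposited 1 table of log2 expression values with a column per array; the log2 unit was read from the range of the values, since the log base is not stated. RMA and MAS5 are both named, per the submitters' processing notes, without a role for either, and their versions are not given in the sources used here. The arrays differed by little in median and quartiles, so the values were used as deposited, with no further normalization. There were 0 columns of other samples. Detection calls were not used here, so a low value cannot be separated from background on its own. For every gene, the size of a change is uncertain where a group mean lies below the median of all probe sets (4.62).

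Groups and replicate numbers came from the sample titles, which call the replicates biological; nothing more is said of how they were made, so the p values measure the spread between these cultures. The design, the gene lists, the rule for named genes and most of the other settings listed further on were fixed before the data were examined. The chromosome analysis, the block tests and the alternatives that leave block genes out were chosen after seeing the data.

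Of 45101 probe sets, 64 array controls were left out and 45037 were tested. Gene symbols came from the platform annotation, which gave 34945 probe sets 1 symbol, 932 several and 9160 none; 34741 of those with 1 symbol were matched through their Entrez identifier to a RefSeq table of the GRCm38.p6 assembly for current symbols and gene order. No build is named with the values, so no coordinates are given. A gene was represented by the probe set with the highest mean over the 6 arrays among those with its symbol alone, giving 18193 genes; in 37 genes, probe sets past the test went in different directions.

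Differences between the groups were tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, equal weights), two-sided, with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05. The fit had 4 residual degrees of freedom and a prior of 3.08. A 2-fold change is a log2 fold change of at least 1 in size on the deposited scale. Fold changes are knockout minus wild-type.

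The 26 gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. None of the 10 list calls made with the preset correlation held with an estimated correlation. The latter test also relies on the 4 residual degrees of freedom of the fit, which the preset test does not. A call lost with it therefore need not reflect correlated members. Adjusting over the list alone means Benjamini-Hochberg over the members of that list. Lists share some genes, for example 3 between imprinted and trophoblast genes. The endoderm, trophoblast, mesoderm, neural and fibroblast lists served as markers of other cells an ES culture could hold.

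Named genes were Med23, Bmp4, Id1, Id2, Id3, Pou5f1, Nanog and Sox2, the 12 largest rises and the 12 largest falls, and up to 4 members of each list with the largest change past the threshold, or the 2 with the lowest p where none passed. The largest changes were taken among genes whose groups did not overlap and whose higher group mean was above the median of all probe sets (1456 higher and 1758 lower). Predicted genes and clones were skipped, 0 among the rises and 2 among the falls. Genes named for their place at the ends of or within chromosome blocks, and further Y-linked genes, were chosen after their values were seen.

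The block analysis used genes with a mean log2 value above 7, limited fold changes to ±1.5, split each chromosome repeatedly where the mean of a stretch differed from the rest by a statistic above 6, with at least 10 genes per stretch, and called stretches with a median at or below -0.4 low. The same step was run on 100 shuffled gene orders. Data were simulated with independent noise per probe set and the same moderated spread in both groups. The test recovered 44% of 50 probe sets changed by 0.5 (log2), 98% of those changed by 1, 100% by 1.5 and 96% by 2. There were 9 false calls among the unchanged probe sets. Fewer probe sets were changed there than were called in the real data, and the real groups differed in spread, so recovery in the real data may differ. A list moved on purpose was called and 0 of 26 unmoved lists were. Because the noise was independent, this says nothing of lists whose members are correlated. All 3 simulated low blocks, each of 30 genes lowered by 0.8 (log2), were found. Shorter blocks and blocks lowered by less were not simulated, so this says nothing of how readily those are found.

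Alternatives tried were quantile normalization, centring each array on its median, keeping only probe sets above the median brightness, eBayes with trend and robust, array weights, no moderation of the variance, the replicate number as a block, leaving out each array, and the mean of all probe sets of a gene. Added after seeing the data were leaving block genes out of the counts and lists and subtracting the median of a block from its genes. Alternative floors were not run, because the values were already logged. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.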

Results

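Gene expression was measured in mouse embryonic stem (ES) cells of the 129SV strain, either wild-type or lacking Med23, a subunit of the Mediator complex that links transcription factors to RNA polymerase II. Each group held 3 arrays, described in the labels as biological replicates, and all cells were harvested after 24 hours in fresh complete medium. The deposited log2 values of 45037 probe sets were compared, and the median per array lay between 4.61 and 4.64. Values correlated at 0.9978 to 0.9981 among the knockout arrays and at 0.993 to 0.9974 among the wild-type arrays, against at most 0.9911 between the groups. Wild-type replicate 1 stood apart from the rest of its group. It had 752 probe sets at least 2-fold below the mean of its fellow replicates and 1 at least 2-fold above that mean. The number of arrays limits the precision of every value below.

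The targeted gene was examined first. Med23, read by 1 probe set, was 8.95, 8.86 and 8.84 (log2) in wild-type replicates 1, 2 and 3 and 7.40, 7.37 and 7.33 in knockout replicates 1, 2 and 3. The group means were 8.88 ± 0.05 and 7.37 ± 0.04 (SD, n = 3 each), a log2 fold change of -1.52 (SE 0.06, limma adjusted p = 2.69e-05), or 2.86-fold lower in the knockout. The knockout mean lay above the median of all probe sets (4.62) and close to the upper quartiles of the knockout arrays (7.32 to 7.34). It was thus not a low value on these arrays. The position of the probe set relative to the deleted part of the gene is not given in the sources used here. What the remaining signal stems from therefore cannot be told.

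The comparison of knockout with wild-type cells asks how loss of Med23 alters expression in ES cells under steady culture, with BMP signalling and neural differentiation named in the study's title. Y-linked genes and stretches of several chromosomes also differed between the groups, as described further on. An effect of Med23 on a gene therefore cannot be told apart from another difference between the cell lines. The growth factor gene Bmp4 and the BMP target genes Id1 and Id2, which encode inhibitors of basic helix-loop-helix factors, were 2.69-fold to 3.18-fold lower in the knockout. Their relative Id3 was 1.49-fold lower. Bmp4 lies in a stretch of chromosome 14 whose genes were lower together, with a median log2 fold change of -0.76. Among the named genes, the immediate early transcription factor gene Egr1 showed the largest measured fall, from 9.86 ± 0.14 to 4.98 ± 0.12 (SD, n = 3). Its log2 fold change was -4.88 (SE 0.10, limma adjusted p = 5.20e-06). Of 29 measured genes of extraembryonic and definitive endoderm, 19 fell and none rose past the test. The transcripts of the pluripotency factors Pou5f1, Nanog and Sox2 did not pass the test. The Y-linked genes Eif2s3y and Uba1y rose from 3.04 and 2.82 in wild-type arrays to 9.87 and 9.02 in knockout arrays.

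In numbers, 3013 probe sets rose and 3346 fell at an adjusted p under 0.05, of which 208 rose and 599 fell at least 2-fold. With 1 probe set per gene, 1551 of 18193 genes rose and 1890 fell, 123 and 352 of them at least 2-fold. Leaving out wild-type replicate 1, the array that stood apart, gave 3494 probe sets higher and 3613 lower. The count of higher probe sets moved most when a knockout array was left out: it was 1710 without knockout replicate 1, 1497 without knockout replicate 2 and 1549 without knockout replicate 3, and it was 1826 without wild-type replicate 2.

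Among the 12 largest rises, 4 were Y-linked genes: Eif2s3y, which encodes a translation initiation factor subunit (log2 fold change 6.83), Uba1y (6.20) and the histone demethylase genes Kdm5d (2.77) and Uty (2.76). In wild-type arrays their means lay between 2.30 and 3.16, below the median of all probe sets of 4.62. Of 9 measured Y-linked genes, chosen after seeing the data, Usp9y also rose, to a mean of 4.43 in the knockout, and Zfy2, Sry, Tspy-ps and Orly did not pass the test. The other 8 rises were Dpys, a pyrimidine-degrading enzyme gene (4.25), the calpain protease gene Capn3 (4.08), Kbtbd11 (3.92), Dusp27 (3.70), Tmem87a (3.21), Dgkeos (2.41), Grb10, an imprinted growth-inhibiting adaptor gene (2.33), and the phospholipase gene Pla2g1b (2.30). In wild-type arrays the means of Capn3, Kbtbd11, Dusp27 and Dgkeos also lay below 4.62, so the sizes of the changes of these and the 4 Y-linked genes, and their order, rest on values that cannot be separated from background. Of the probe sets of each gene, 1 of 3 passed the test for Dpys, 1 of 3 for Kdm5d and 1 of 2 for Dgkeos. Adjusted p values of the 12 genes ran from 5.20e-06 for Uba1y to 0.000543 for Uty.

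After Egr1, the largest falls were those of Nod1, an innate immune receptor gene (log2 fold change -4.43), the oligodendrocyte lineage factor gene Olig1 (-4.15), the basement membrane collagen genes Col4a2 (-3.71) and Col4a1 (-3.41), the proteoglycan gene Srgn (-3.56), Pla2g7 (-3.52), the endocytic adaptor gene Dab2 (-3.38), Xaf1 (-3.15), the endocytic receptor gene Cubn (-3.11), the Nodal antagonist gene Lefty2 (-3.09) and Perp (-2.80). The knockout means of Nod1, Olig1, Pla2g7 and Xaf1 lay below the median of all probe sets. The sizes of their falls, and the order of the falls including the place of Egr1, are likewise uncertain. Another probe set of Xaf1 passed the test in the opposite direction, so the change of that gene depends on the probe set. Col4a1 and Col4a2 lie side by side within a stretch of chromosome 8 whose genes were lower together, described further on, and both fell much further than its median of -0.54.

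**Figure D1:**
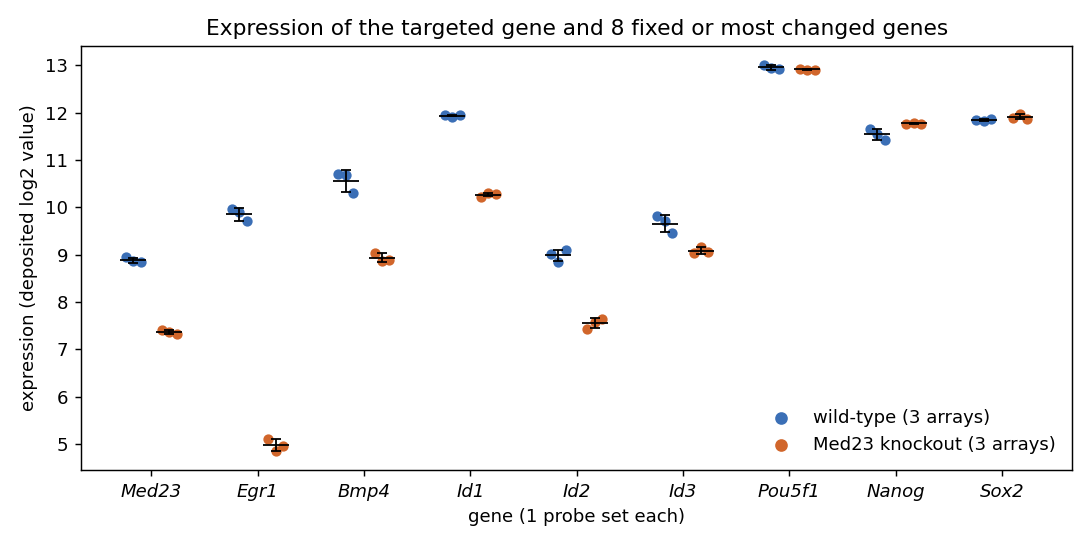
Deposited log2 expression (vertical axis) of 9 genes (horizontal axis) on the 3 wild-type and 3 Med23 knockout arrays, with points for arrays and black bars for the group mean ± SD. Med23, Egr1, Bmp4, Id1, Id2 and Id3 lie lower on all 3 knockout arrays, while the Pou5f1 means are 12.96 and 12.92.

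BMP pathway genes were examined in a list of targets and a list of pathway components. Of 17 measured BMP response genes, 7 fell, 1 rose and 9 did not pass the test; adjusted over the list alone, 8 fell and 1 rose. Id1 went from 11.94 ± 0.02 to 10.27 ± 0.04 (SD, n = 3; log2 fold change -1.67, SE 0.06, adjusted p = 1.84e-05) and Id2 from 8.98 ± 0.12 to 7.55 ± 0.11 (-1.43, SE 0.09, adjusted p = 0.000131). Dusp9, a MAP kinase phosphatase gene, fell by 0.90, Id4 by 0.82 and Id3 by 0.57. The list's median log2 fold change was -0.27 (camera, adjusted p = 0.0131), with adjusted p = 0.313 with an estimated correlation. One of the 7 genes that fell, the Notch and BMP target Hey1, lies in the low stretch of chromosome 3.

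Of 32 ligands, receptors and modulators of the BMP pathway, 4 fell, 2 rose and 26 did not pass the test; adjusted over the list alone, 7 fell and 3 rose. Bmp4 went from 10.56 ± 0.23 to 8.93 ± 0.10 (SD, n = 3; log2 fold change -1.63, SE 0.12, adjusted p = 0.000273), the secreted modulator gene Bmper fell by 2.70, the activin-binding follistatin gene Fst by 0.98 and the receptor gene Bmpr1a by 0.58. The Bmper knockout mean, 2.98, lay below the median of all probe sets, so the size of its fall is uncertain. Bmp4 and Bmpr1a lie in a stretch of chromosome 14 whose 126 brighter genes had a median of -0.76. Bmp4 was the lowest of those 126 genes, and its value minus the stretch's median was -0.87; the value of Bmpr1a minus that median was 0.18. The list as a whole did not pass (median -0.04, camera adjusted p = 0.191).

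Pluripotency genes moved in both directions. Pou5f1 had a log2 fold change of -0.04 (SE 0.06, adjusted p = 0.721), Nanog 0.23 (SE 0.08, adjusted p = 0.0957) and Sox2 0.07 (SE 0.06, adjusted p = 0.523). Sox2 lies in the low stretch of chromosome 3 with a median of -0.60, and its value minus that median was 0.67. Of 29 measured genes of core and naive pluripotency, 4 rose, 5 fell and 20 did not pass; adjusted over the list alone, 7 rose and 6 fell. Fbxo15 rose from 11.16 to 12.16, Pecam1 by 0.69 and Klf2 by 0.62, while Klf4 fell by 0.63 (list median 0.03, camera adjusted p = 0.855). The calls of Pecam1 and Klf2 ended in part of the fits that left out 1 array (adjusted p up to 0.0553 without wild-type replicate 2 and 0.0746 without knockout replicate 3). Of 16 primed epiblast genes, 6 rose and 5 fell, and the same counts held adjusted over the list alone (median -0.09, camera adjusted p = 0.768). Fgf15 (-1.87), Cldn6 (-1.59) and Pim2 (-1.31), the last of them in the low stretch of the X chromosome, fell, whereas the transcription factor gene Zic2 rose by 1.09.

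Neural genes were likewise split. Of 45 measured neuroectoderm and neural genes, 9 rose, 7 fell and 29 did not pass; adjusted over the list alone, 9 rose and 10 fell. Pax6, a regulator of eye and brain development, rose from 5.14 ± 0.66 to 7.35 ± 0.06 (SD, n = 3; log2 fold change 2.21, SE 0.29, adjusted p = 0.00299), and Zic5 rose by 1.16. Olig2 fell by 2.34 and the microtubule-associated protein gene Map2 by 1.49. Their knockout means, 3.36 and 3.38, lay below the median of all probe sets, so the sizes of these falls are uncertain. Of 4 Map2 probe sets, 1 passed the test. Zic2 and Zic5 rose although they lie in a low stretch of chromosome 14 with a median of -0.68. The list did not pass (camera adjusted p = 0.856), and its median (-0.01), mean (0.04) and camera direction (higher) differed in sign.

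Markers of other cell types that an ES culture can hold were led by endoderm. Of 29 measured endoderm genes, 19 fell, none rose and 10 did not pass; adjusted over the list alone, 19 fell and 1 rose. Col4a2, Col4a1, Dab2 and Cubn fell by 3.71, 3.41, 3.38 and 3.11. The list's median log2 fold change was -1.22 (camera, adjusted p = 3.05e-10), with adjusted p = 0.25 with an estimated correlation. The median was -1.05 without wild-type replicate 1, and 3 of the 19 genes that fell, Col4a1, Col4a2 and Gata4, lie in low stretches of chromosomes 8 and 14; without members in such stretches, 16 of 26 genes fell and the median was -0.87.

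Of 20 trophoblast genes, 10 fell, none rose and 10 did not pass; adjusted over the list alone, 11 fell and 1 rose. The simple-epithelium keratin genes Krt8, Krt7 and Krt18 fell (-2.52, -1.91 and -1.67), and so did Lgals3 (-1.59), which lies in the same chromosome 14 stretch as Bmp4 (list median -0.36, camera adjusted p = 0.000149, adjusted p = 0.25 with an estimated correlation). Of 30 primitive streak and mesoderm genes, 4 fell and none rose, also when adjusted over the list alone. These were the receptor gene Pdgfra (-2.19), which the endoderm list also holds, Tcf15 (-0.92), Twist1 (-0.61) and Snai1 (-0.41), and the list did not pass (median -0.03, camera adjusted p = 0.165). Of 24 fibroblast markers, which stand for feeder cells, 4 fell and 1 rose; adjusted over the list alone, 5 fell and 1 rose (median -0.05, camera adjusted p = 0.138). Tgfbi, Thy1, Twist1 and Timp3 fell by 0.79, 0.73, 0.61 and 0.51. Leaving out 1 array ended the calls of Snai1 and Thy1 in part of the fits (adjusted p up to 0.134 and 0.0672, both without knockout replicate 2), and 17 of the 30 mesoderm and 14 of the 24 fibroblast genes, Snai1 among them, were at or below the median of all probe sets in both groups.

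Immediate early genes are induced within minutes of growth factor stimulation. The list of immediate early and serum response genes also holds transcription factor genes such as Elk1, Elk3 and Elk4, so not every member is one. Of its 31 measured members, 18 fell, none rose and 13 did not pass. Adjusted over the list alone, 21 fell and 1 rose. Besides Egr1, the AP-1 subunit gene Jun fell by 2.06, and the matricellular protein genes Ccn1 and Ccn2 fell (-1.78 and -1.38). The median was -0.46 (camera, adjusted p = 4.78e-10), with adjusted p = 0.25 with an estimated correlation, and no member lay in a low stretch. Of 23 SRF and cytoskeletal targets, 8 fell and 1 rose (9 and 3 adjusted over the list alone; median -0.17, camera adjusted p = 0.0964), with Tagln, Cald1 and Fhl1 lower by -1.61, -0.73 and -0.71 and the myosin light chain gene Myl9 higher by 0.90.

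Of 17 genes of FGF and ERK feedback, 7 fell and 2 rose, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.0994). Phlda1 fell by 1.98, Spry2 by 0.92, Epha2 by 0.70 and the ERK phosphatase gene Dusp6 by 0.56; Spry2 lies in the second low stretch of chromosome 14. Of 22 genes of Nodal and TGF-beta signalling, 7 fell and none rose, and 11 fell adjusted over the list alone (median -0.18, camera adjusted p = 0.000149, adjusted p = 0.25 with an estimated correlation). The Nodal antagonist genes Lefty2 and Lefty1 fell (-3.09 and -2.41), as did Inhbb (-1.11) and Skil (-1.01), the latter in the low stretch of chromosome 3. Of 22 WNT genes, 7 fell and 4 rose (7 and 5 adjusted over the list alone; median -0.14, camera adjusted p = 0.0994), among them the WNT antagonist gene Dkk1 (-2.79), Wnt6 (-0.88), Ccnd1 (-0.71) and Sp5 (-0.57). Of 22 Notch pathway genes, 5 fell and 2 rose (10 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.0848), and Hes6 fell from 8.23 to 7.23, with Hey1, Mfng and Hes1 at -0.55, -0.54 and -0.54. The size of the Dkk1 fall is uncertain, since its knockout mean, 3.66, lay below the median of all probe sets. The Sp5 and Hes1 calls ended in part of the fits that left out 1 array (adjusted p up to 0.0909 without wild-type replicate 2 and 0.0672 without knockout replicate 2).

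Of 24 p53 targets and stress genes, 13 fell and 3 rose (13 and 5 adjusted over the list alone; median -0.29, camera adjusted p = 0.0017, adjusted p = 0.313 with an estimated correlation). Perp fell by 2.80, Zmat3, in the low stretch of chromosome 3, by 1.16 and Btg2 by 0.98, while Chac1 rose by 0.90. Of 33 cell cycle genes, 4 fell and 3 rose (5 and 5 adjusted over the list alone; camera adjusted p = 0.813). The cyclin genes Ccnd2, Ccnd1 and Ccne1 fell by 2.67, 0.71 and 0.60, and the inhibitor gene Cdkn2b by 0.54, a call that ended in 4 of the fits that left out 1 array (adjusted p up to 0.125 without knockout replicate 2). Of 33 Mediator subunit genes, 4 fell and 3 rose (6 and 4 adjusted over the list alone; camera adjusted p = 0.856). Besides Med23, Med14 fell by 1.16 and lies in the low stretch of the X chromosome, whereas Med21 and Med29 rose by 0.61 and 0.44; 2 other probe sets of Med29 passed in the opposite direction. The Mediator list's median (0.05) and camera direction (higher) differed in sign from its mean (-0.01).

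**Figure D2:**
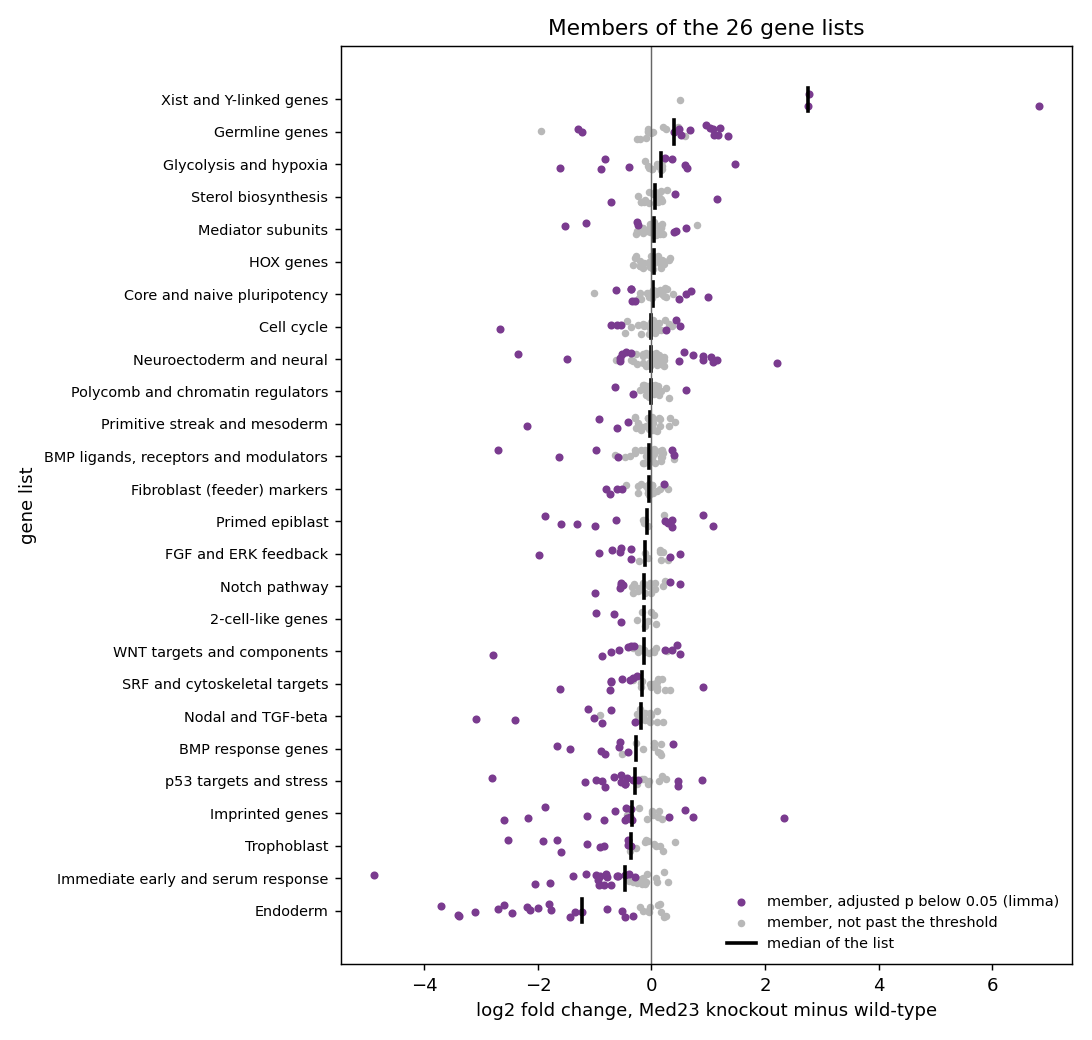
Log2 fold change (knockout minus wild-type, horizontal axis) of each measured member of the 26 gene lists (vertical axis), with purple points past an adjusted p of 0.05 in limma, grey points not past it, and black bars for list medians. The endoderm median lies lowest at -1.22 and the median of Xist and Y-linked genes highest at 2.76.

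Position along the chromosomes was examined after seeing the data, over genes with a mean log2 value above 7. A segmentation of fold changes in gene order found 6 stretches, called blocks here, whose median was at or below -0.4, and none that was higher by as much. On chromosome 14, block 1 ran from Selenok to Pinx1 (126 genes, median -0.76, 112 of them lower past the test) and block 2 from Mycbp2 to Tmtc4 (20 genes, median -0.68). Block 3 ran from Srbd1 to Mettl4 on chromosome 17 (13 genes, -0.89), block 4 from Zc2hc1a to Exosc9 on chromosome 3 (47 genes, -0.60), block 5 from Arhgef18 to Tdrp on chromosome 8 (39 genes, -0.54) and block 6 from Vamp7 to Kdm6a on the X chromosome (37 genes, -0.72). In each block the median of every knockout array lay below that of every wild-type array. The 282 genes in blocks made up 3.70% of the genes at this brightness and held 22.2% of their falls, and 80.9% of them fell, against 10.9% outside. Because blocks were defined by low fold changes, these shares and the lower knockout medians follow largely from the definition. Over all 18193 genes, 308 of the 1890 that fell lie in blocks, and with block genes left out 1540 rose and 1582 fell.

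**Figure D3:**
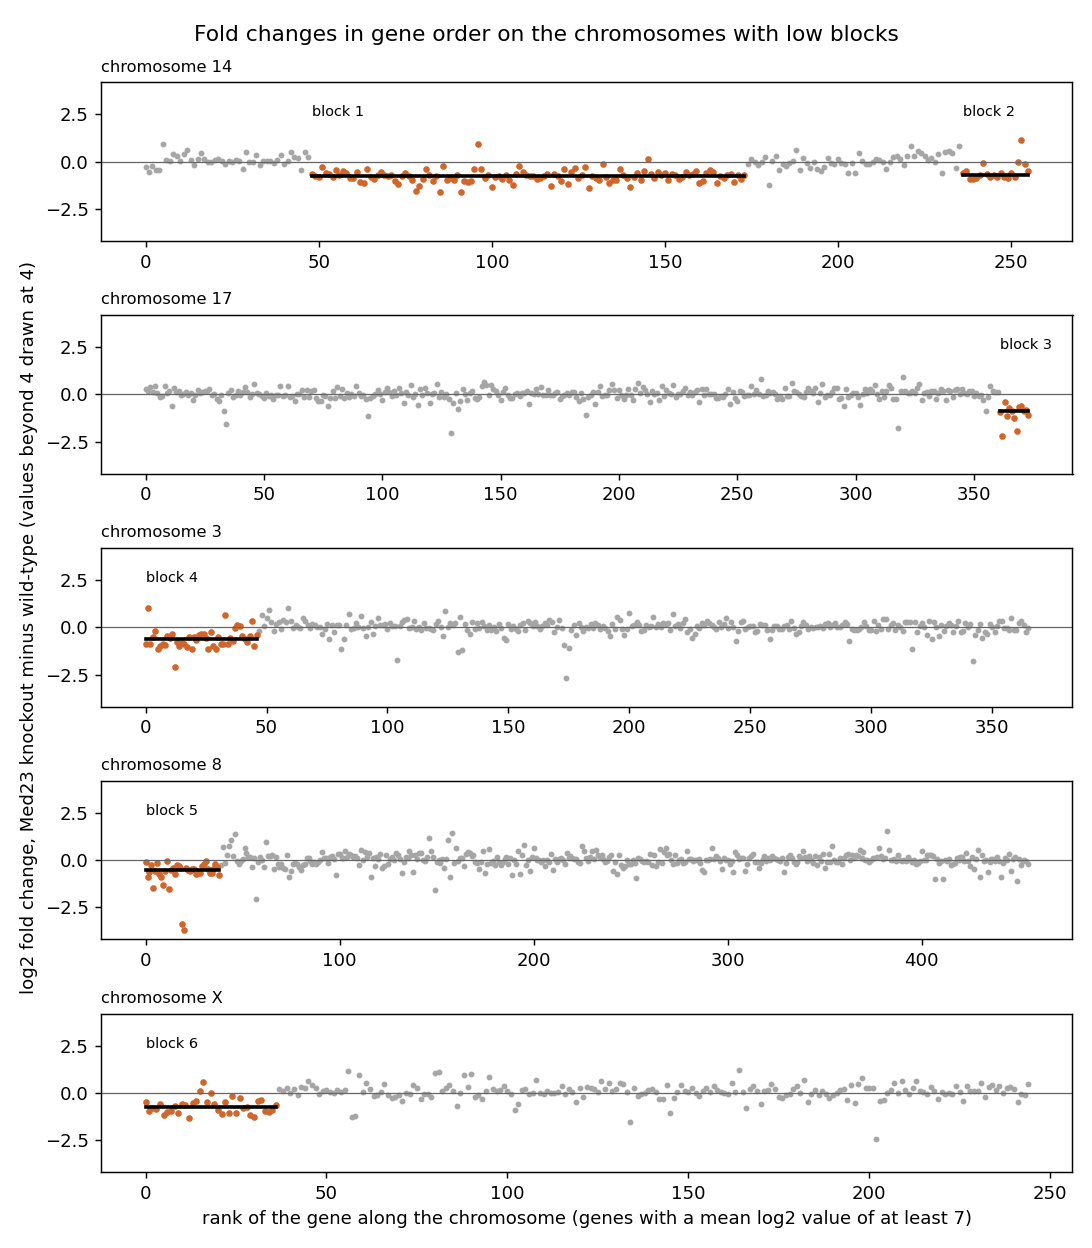
Log2 fold change (knockout minus wild-type, vertical axes) of genes with a mean log2 value above 7, by rank along chromosomes 14, 17, 3, 8 and X (horizontal axes), with orange points in blocks, grey points elsewhere and black lines for block medians. The block medians run from -0.89 to -0.54.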

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

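The tests that leave out block genes or subtract a block's median were chosen after seeing the data, and the others before. Med23 kept its direction and its call in every alternative, from -1.54 to -1.49. The 2-fold counts stayed within 1.5 times, at 180 to 215 higher and 528 to 680 lower. Replicate numbers did not pair the arrays: deviations from the group means correlated at -0.13, -0.06 and 0.00083 for numbers 1, 2 and 3. With the replicate block, 1915 probe sets and 1000 genes were higher, against 3013 and 1551, fewer degrees of freedom being left. Leaving out 1 array gave 1497 to 3494 probe sets and 800 to 1841 genes higher. Both counts were lowest without knockout replicate 2 and highest without wild-type replicate 1, where they exceeded those of the full fit. Having fewer arrays therefore does not alone account for the range, and the cause was not tested. Of the 3441 genes past the test, 2073 to 3057 were still called in the same direction. Scalings moved the median fold change of all probe sets between 0.02 and 0.03.

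The gene lists depended most on the set test. With an estimated correlation, 0 lists were called higher and 0 lower, against 2 and 8: the adjusted p was 0.25 for the endoderm, trophoblast, immediate early, Nodal and TGF-beta, germline, and Xist and Y-linked lists, 0.308 for imprinted genes, and 0.313 for the BMP response, 2-cell-like and p53 lists. This test allows for the correlation between members, estimated from 6 arrays. It also relies on the 4 residual degrees of freedom of the fit, which the test with the preset correlation does not. The estimate was 0.00123 for the germline list and -0.195 for the Xist and Y-linked list, below the preset 0.01. A higher correlation therefore does not account for the loss of their calls. With fry, which compares no list with other genes, 16 lists were called lower, with the 8 additional ones at adjusted p = 0.00687 (BMP ligands, receptors and modulators), 0.0063 (mesoderm), 0.0122 (fibroblast), 0.0244 (SRF), 0.016 (FGF and ERK), 0.0133 (WNT), 0.0163 (Notch) and 0.0337 (cell cycle). Over probe sets above the median brightness, which leave fewer members, 1 list was called higher, and the adjusted p was 0.816 for 2-cell-like, 0.16 for imprinted and 0.0537 for Xist and Y-linked genes. The 2-cell-like list also lost its call with trend and robust (adjusted p = 0.0929) and ranged from 0.0214 to 0.115 when 1 array was left out; the cause was not tested. The FGF and ERK list passed with the mean of all probe sets of a gene (adjusted p = 0.0484).

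Of 112 named genes, 87 kept their call in every alternative, 20 lost it in at least 1 and 2, Nanog and Hoxa11, gained one. Id3, Fst, Bmpr1a, Map2, Tgfbi, Hes6, Hey1, Mfng and Hormad1 lost it only with no moderation of the variance (adjusted p 0.0537 to 0.0908) and Xaf1 only with the mean of its probe sets (-0.10, adjusted p = 0.568). Pecam1, Klf2, Snai1, Thy1, Sp5, Hes1, Cdkn2b, Insig1, Bmi1 and Jarid2 lost it when some single arrays were left out. All of these but Jarid2 also lost it with no moderation of the variance. With the replicate block, the calls of Cdkn2b and Jarid2 ended too (limma adjusted p = 0.0643 and 0.0504). Snai1 also lost its call with array weights (0.0599), Klf2 with trend and robust (0.0529) and Bmi1 with the mean of its probe sets (0.0615). Med29 turned to -0.16 with the mean of its probe sets, which disagree in direction. Minus the median of their block, Bmpr1a, Hey1, Fdft1 and Kdm6a turned to 0.18, 0.0443, 0.0518 and 0.0887. Other falls shrank by more than 1.5 times on this measure: Bmp4 to -0.87, Lgals3 to -0.83, Pim2 to -0.58, Zmat3 to -0.57, Med14 to -0.43, Skil to -0.41, Spry2 to -0.24, Ero1a to -0.13 and Gata4 to -0.02. The rises of Zic2 and Zic5 grew to 1.77 and 1.84. The unmoderated variance was not run for the list tests, which have their own variance step. Med23 has 1 probe set, so no other was tried, and floors were not varied because the values are logged.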

Other observations

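Imprinted genes, which are expressed from 1 parental copy, changed in both directions. Of 26 measured, 12 fell and 4 rose (15 and 5 adjusted over the list alone; median -0.34, camera adjusted p = 0.0176, adjusted p = 0.308 with an estimated correlation). Peg3, Nnat and Plagl1 fell (-2.59, -2.18 and -1.88), and Grb10 rose by 2.33. The size of the Nnat fall is uncertain, since its knockout mean, 3.78, lay below the median of all probe sets. Of 3 Plagl1 probe sets, 1 passed the test. Of 27 germline genes, 11 rose and 2 fell (14 and 4 adjusted over the list alone; median 0.40, camera adjusted p = 0.0168, adjusted p = 0.25 with an estimated correlation). The piRNA pathway gene Mael and the meiotic gene Hormad1 rose by 1.35 and 1.21, and the X-linked homeobox genes Rhox6 and Rhox9 fell (-1.29 and -1.23). Of 10 genes of 2-cell-like cells, 3 fell and none rose, also adjusted over the list alone: Usp17la (-0.98), Tcstv1 (-0.66) and Arg2 (-0.53; median -0.13, camera adjusted p = 0.0382, adjusted p = 0.313 with an estimated correlation). Of these 10 genes, 7 were at or below the median of all probe sets in both groups, Tcstv1 and Arg2 among them, so the values say little of this list.

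Metabolic and chromatin lists did not pass as lists. Of 23 genes of glycolysis and hypoxia, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.257), with the mitophagy receptor gene Bnip3 up by 1.46 and P4ha2, Ero1a and Egln3 at -1.61, -0.90 and -0.83; Ero1a lies in block 1. Of 19 sterol genes, 2 rose, Stard4 (1.15) and Insig1 (0.41), and 1 fell, Fdft1 (-0.71), which lies in block 1. The Insig1 call ended in part of the fits that left out 1 array (adjusted p up to 0.0853, without knockout replicate 3), and the counts were the same adjusted over the list alone (camera adjusted p = 0.663). Of 25 polycomb and chromatin regulators, Bmi1 rose by 0.61 and Kdm6a (-0.63, in block 6) and Jarid2 (-0.32) fell, also adjusted over the list alone (camera adjusted p = 0.813; the median of -0.01 and the mean of 0.0025 differ in sign). The calls of Bmi1 and Jarid2 also ended in part of these fits (up to 0.0535 without knockout replicate 1 and 0.0641 without knockout replicate 3). None of 32 HOX genes passed in limma with either adjustment, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.856); Hoxa11 was at -0.32 and Hoxb1 at -0.27 (adjusted p = 0.0879 and 0.106), both among the 23 HOX genes at or below the median of all probe sets in both groups.

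In the paragraphs that follow, the tests of 2 active X chromosomes, arrays swapped between the groups, fewer differentiated cells of every kind, fewer endoderm-like cells, the length of chance runs, their share and number of genes past the test and lower, the share of endoderm falls in blocks, and the other splits of the arrays were chosen after the result was seen; the other tests had bounds written before they were run. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, reached the real counts of 6359 probe sets, 3441 genes and 807 probe sets at 2-fold, and the highest count of the other splits was 0 in each case. Every other split mixes the genotypes, which adds the difference between them to the spread. Counts of 0 could thus be foreseen and give the real counts no support.

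The blocks of neighbouring genes that were lower in the knockout were weighed first. A lower copy number of the whole of chromosome 14 is argued against, since 60.3% of its windows of 20 genes lay below -0.2 where at least 90% was called for, and so is wild-type replicate 1 as the source, since the median of block genes was -0.75 without it and -0.72 with it. Shuffled gene orders gave up to 2 low blocks against the 6 observed, more than the 1 allowed beforehand. Their longest held 13 genes, as many as block 3, and up to 70% of the genes of one were past the test and lower, against 100% in block 3 but no more than that in blocks 2 and 5; none held more than 8 such genes, against at least 13 in each of the 6 blocks, which argues against chance runs. A candidate explanation is that chromosome segments differ in copy number between the cell lines: of 117 dimmer genes in the blocks, which had not defined them, 87.2% lay below the median of dimmer genes outside. Block medians run from -0.89 to -0.54, against -0.58 for 2 copies set against 3 and -1 for 1 copy set against 2, so they single out neither; copy number was not measured here, and an effect of Med23 on whole segments stays untested.

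Of 9 measured Y-linked genes, Eif2s3y, Uba1y, Kdm5d and Uty had knockout means above the median of all probe sets and lay below it on all wild-type arrays, Usp9y rose to 4.43, below that median, and Zfy2, Tspy-ps, Orly and Sry did not pass the test (adjusted p = 0.145, 0.152, 0.809 and 0.244). Of the 4 genes in the list of Xist and Y-linked genes 3 rose, or 4 adjusted over the list alone (median 2.76, camera adjusted p = 0.000149, adjusted p = 0.25 with an estimated correlation), and Xist was at 0.51 (adjusted p = 0.0668), 0.03 and -0.03 (adjusted p = 0.803 and 0.905) by its 3 probe sets. Its antisense gene Tsix rose by 1.24 (adjusted p = 0.00141). As a test of swapped arrays, 0 arrays had a Med23 value nearer the mean of the other group than that of the rest of their own. An exchange of all arrays would also give 0, and swapped single arrays would not give a difference seen on every array. The test therefore decides nothing about this pattern. The presence of 2 active X chromosomes in the wild-type cells is argued against, since X-linked genes outside block 6 had a median 0.0491 above that of autosomal genes. Absence of a Y chromosome from the wild-type cells may account for the pattern, yet 1 gene, Sry, went against the bound set beforehand by lying above that median in both groups. Its means were 5.24 and 5.40, so its level does not follow those of the 4 genes; the bound was a poor one, and the question stays open, as does any difference between the lines beyond Med23.

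Of 29 endoderm genes, 19 were lower in the knockout past the test and 10 did not pass; the list's call ended with an estimated correlation (adjusted p = 0.25). Wild-type replicate 1 as the source is argued against by a list median of -1.05 without it and -1.22 with it. The blocks held 15.8% of the endoderm genes that fell, which argues against them as the place of most of the falls; the median without block members, -0.87, lay between the bounds set beforehand, so a part played by the blocks stays open. Fewer endoderm-like cells in the knockout cultures stays open: the 19 falls are the pattern itself and give this no support, bulk RNA cannot part fewer such cells from less RNA per cell, and an effect of Med23 itself stays open as well. Fewer differentiated cells of every kind also stays open: trophoblast genes fell too (10 lower, none higher) and neural genes went both ways (9 higher, 7 lower), while the mesoderm and fibroblast medians, the lower at -0.0512, decide nothing because 17 of 30 and 14 of 24 members were at or below the median signal in both groups.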
